A study of Arabidopsis thaliana with 29 samples.

How the data were processed

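The series holds 29 Affymetrix expression arrays of Arabidopsis thaliana leaf RNA, one per sample, in 10 groups set by genotype, inoculation and time. Per the submitters' processing notes the authors made the values with GCRMA, for which no version is stated, and the deposited values are log2 signals per probe set, normalised across arrays. The authors also left out 1 array, replicate 3 of inoculated Col-0 at 24 h, after a quality check of their own. The file holds 22810 probe sets, of which 64 are control probe sets and 22746 were tested. The lowest value in the file, 2.23, is shared by 1810 probe sets on every array and by 8461 on some array, and between 25.5% and 30.0% of probe sets lie at it on each array. For 991 probe sets the lowest value lies above that floor and is still shared by several arrays, and 7498 have a higher value that several arrays share. Where all arrays of the lower group share one value, or any of them lies at the floor, the fold is therefore written as at least that size.

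Probe sets were named from the table of genes supplied with the series and from a reference annotation, joined by gene identifier: 13513 have one gene, 503 have several and were not named, and 8730 are not listed. A locus could be given to 13436, for 13286 distinct loci. The other 150 probe sets are further ones of loci already counted, and 1551 of the 13436 probe sets have a symbol besides the locus name. A gene is represented by its probe set with the highest mean over all arrays. The tables pair no probe set with the mutated genes AOS, EIN2 and ICS1, nor with PR1, VSP2, PAD3, JAZ10, ORA59 and ERS2, so these are not reported.

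Groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with one mean per group on all 29 arrays (residual df 19), moderated variances with an intensity trend (prior df 0.855) and two-sided tests. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set passed at an adjusted p under 0.05. Errors of log2 differences are standard errors from this model. The comparisons were inoculated against mock Col-0 at each time, each mutant against inoculated Col-0 at each time, mock Col-0 at 24 h against 9 h, the difference of each of these effects between the times, and each pair of mutants at each time, for which only named genes are given. The labels name 3 independent experiments, and the replicate number was taken as the experiment; the model has no block for it, and counts with that block are given beside the results. Arrays of one number resembled each other after group means were removed (mean r = 0.388 over 126 pairs, against -0.19 over 252 pairs of different numbers). Removing group means ties the second value to the first with the opposite sign, so it adds no separate support for the pairing. The resemblance did not hold everywhere: inoculated Col-0 at 24 h had r from -0.104 to 0.388 with arrays of its number at that time. At 9 h replicate 2 of dde2-2 had r = -0.056 with that of inoculated Col-0, -0.182 with that of sid2-2 and 0.215 with that of ein2-1. Inoculated Col-0 at 24 h holds 2 arrays, whose values after removal of the group mean are equal and opposite and carry nothing of experiment 3. Its low r therefore cannot decide whether its pairing holds. The pairing of all these arrays, and blocked counts that use them, stay uncertain.

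Genes named in the text follow a rule set before the data were examined, as were the comparisons, the tests and 25 gene lists: the mutated genes and 7 markers, of which only PDF1.2 could be named; per comparison up to 10 of the 10 largest rises and 10 largest falls among probe sets that passed, had one gene and did not overlap between the groups; and up to 4 called members per list. Genes whose call rested on a single array were mostly left out, a choice made after those refits were seen. Of 374 loci in the 25 lists 51 were measured under a name. A further 17 lists were drawn up after the annotation was read and before any comparison was run. Lists with at least 3 measured members, 25 in all, were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over lists within a comparison; camera compares a list with all other probe sets, and fry asks whether its members move one way on balance. The lists described are a choice made after their tests were seen. Those set beforehand are pattern-triggered immunity, salicylate response markers, jasmonate and ethylene defence, jasmonate repressors and breakdown, photosynthesis, and abscisic acid and water deficit. Those from the annotation are U-box ubiquitin ligases, calmodulin-like proteins, UDP-glycosyltransferases, tetrapyrrole and chlorophyll synthesis, chloroplast-encoded genes, jasmonate metabolism and regulators, expansins and xyloglucan hydrolases, autophagy genes, and SWEET transporters; genes on both kinds of list count in both.

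The share of the Col-0 response in each mutant was computed from arrays of one experiment at a time, on probe sets chosen in the other experiments by a log2 difference of at least 1, as the mean signed distance of the mutant from mock Col-0 over that of inoculated Col-0. Experiments were compared in pairs on one list, chosen by the same minimum in the third experiment; lists chosen separately for each experiment were dropped, since they favour strong responders where a weak experiment takes part in the choice. Medians of sets of probe sets were compared with those of 10000 random sets matched on mean signal in 20 bins; such random sets do not share the correlation of real gene sets, so their range is descriptive.

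The methods were tested on simulated data, drawn independently for each probe set and array. They hold no correlation between probe sets, no effect of the experiment and the same spread in every group. Errors that such features of the real data may cause were therefore not measured. In the layout of inoculated against mock Col-0 at 9 h, 18% of probe sets changed by 1 log2 unit were recovered. Of those changed by 2 and by 3 log2 units, 64% and 82% were recovered, with 5 false calls. In the layout of dde2-2 against Col-0 at 24 h the same rates were 34%, 60% and 84%, with 7 false calls. Only 50 of 22746 probe sets were changed by each amount, all drawn from those with higher mean signals. The real comparison at 9 h called 2873, and the Benjamini-Hochberg cutoff depends on the share changed. These rates therefore need not hold for the real comparisons, and recovery at low signal was not measured. At a threshold of 0.05 camera called a simulated list of 12 shifted by 1 log2 unit, and 1 of 50 unshifted lists. A simulated share of 60% was estimated as 59.2%. For random sets, 1 of 20 unshifted sets fell outside the 2.5th to 97.5th percentile.

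Alternatives tried were a filter that removes the 40% of probe sets with the lowest means, quantile renormalisation, median centring of each array, no intensity trend, robust variances, array weights, a 2-fold minimum, the experiment as a fixed or random block (consensus correlation 0.332), only the arrays compared, every probe set of a locus, and leaving out each array in turn. Another 3 were added after seeing the data: leaving out experiment 3, leaving out probe sets at the floor on every array, and array weights by the gene-by-gene method, because the default method stopped before it converged. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw array files were not reprocessed, fungal transcripts are not on these arrays, and no function enrichment beyond the lists was tested.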

Results

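Transcript levels were measured in leaves of 3-week-old Arabidopsis thaliana plants inoculated with Alternaria brassicicola, a fungus that kills host cells and feeds on them, or mock inoculated. Droplets of 10 µl holding 100000 spores per ml were placed on leaves at clock hour 10, and leaves were taken 9 h later (clock hour 19) or 24 h later (clock hour 10). Wild type Col-0 was sampled with and without the fungus. Beside it stood inoculated plants of 3 mutants: dde2-2, which lacks allene oxide synthase and makes no jasmonate; ein2-1, which is insensitive to ethylene; and sid2-2, which lacks isochorismate synthase 1 and makes little salicylate. No mutant was mock inoculated, so a difference between a mutant and Col-0 combines the effect of the mutation in uninfected leaves with its effect on the response. Each of the 10 groups holds 3 arrays from 3 independent experiments, except inoculated Col-0 at 24 h, which holds 2 because the authors left out its array of experiment 3 after a quality check. The deposited values are log2 signals of 22746 probe sets, control probe sets set aside. Of these, 13513 could be given one gene. The number of arrays limits the precision of every value given here.

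Time and infection separated the arrays. On the first principal component (35.6% of the variance) the inoculated arrays at 24 h scored from 61.4 to 85.7, the mock arrays at 24 h from 6.17 to 24.3, and all arrays at 9 h from -77.9 to -26.7. On the second (25.4%) the inoculated 9 h arrays of experiment 3 scored from -23.3 to 5.26, those of experiments 1 and 2 from 7.18 to 95.9, and the mock arrays of that time from -84.0 to -37.3. Pairs of experiments were compared on one list of probe sets each, those that differed at least 2-fold between inoculated and mock Col-0 at 9 h in the third experiment. The mean response was 0.99 log2 units in experiment 3 against 2.04 in experiment 1 (3554 probe sets), 0.87 in experiment 3 against 1.61 in experiment 2 (4645), and 1.85 in experiment 2 against 1.92 in experiment 1 (2250). The GAPDH control probe sets gave a 3' minus 5' difference between 1.23 log2 units (ein2-1, 24 h) and 1.73 (mock Col-0, 9 h) as group means. For the actin control probe sets it was larger, between 4.86 (ein2-1, 24 h) and 5.53 (inoculated Col-0, 9 h). For ubiquitin it ranged from 0.35 to 1.28 on single arrays.

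**Figure D1:**
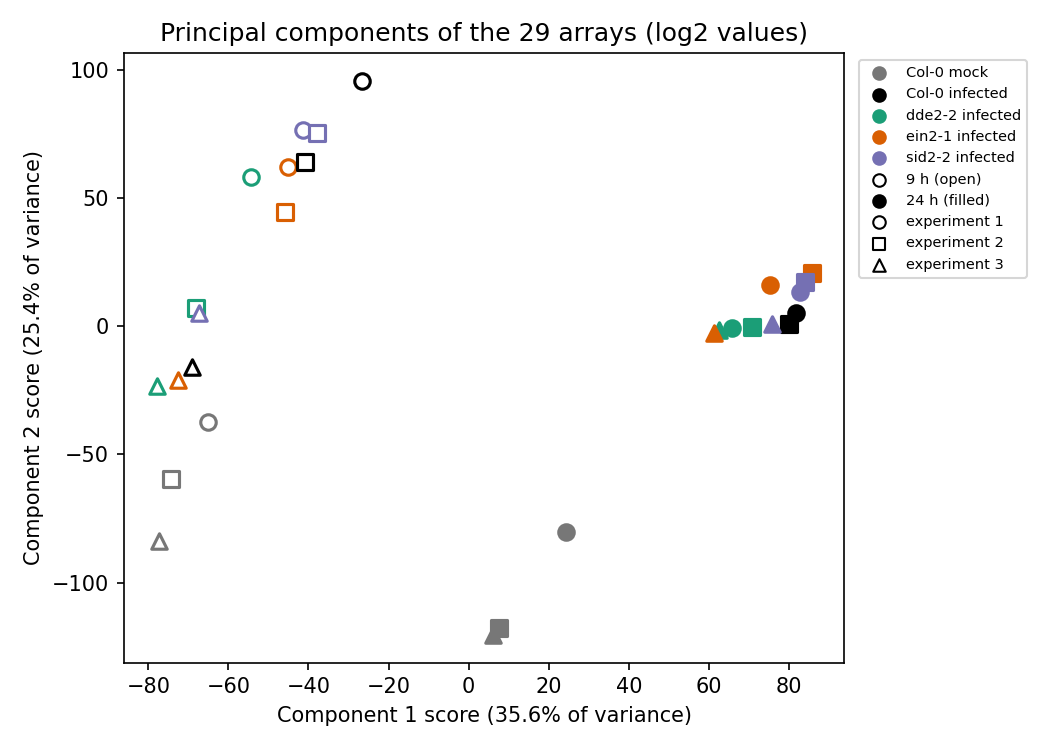
Scores of the 29 arrays on the first and second principal components of the log2 values, coloured by genotype and treatment, open at 9 h and filled at 24 h, with a symbol for each experiment. The inoculated 9 h arrays of experiment 3 (open triangles) score from -23.3 to 5.26 on component 2.

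How wild-type leaves responded early was asked by comparing inoculated with mock Col-0 at 9 h (n = 3 each). The largest rise with one gene was that of AT1G26380, a berberine bridge-like oxidase, at 548-fold (log2 difference 9.10 ± 0.83 SE, adjusted p = 3.53e-07). AT4G37290 rose 435-fold, AT2G23270 rose 243-fold, the peroxidase gene Prx37 (AT4G08770) rose 248-fold, and AT4G12500, a lipid transfer protein gene, rose 139-fold. AT2G04070 and AT2G04050, which encode efflux transporters of the MATE family, rose 121-fold and 116-fold. Falls were smaller: AT1G49010 fell 7.37-fold, AT3G28270 fell 6.25-fold and AT4G12830 fell 5.65-fold. Single inoculated arrays moved some folds over 1.5 times: without replicate 3 AT1G26380, AT4G37290 and Prx37 rose 1140-fold, 653-fold and 524-fold, without replicate 1 AT1G26380 and Prx37 rose 364-fold and 163-fold and AT1G49010 fell 4.49-fold, and without replicate 2 AT4G12500 rose 92.0-fold.

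In the lists of defence genes at 9 h, all 5 measured members of the pattern-triggered immunity list rose (5 adjusted over the list alone), among them the ubiquitin ligase genes PUB23 (AT2G35930; 72.4-fold), PUB24 (AT3G11840; 5.93-fold) and PUB22 (AT3G52450; at least 4.81-fold, since its 3 mock arrays share one low value), with camera adjusted p = 6.17e-08 and 0.0152 with an estimated correlation. Within the 9 U-box ubiquitin ligase genes the same 3 rose and 6 did not pass (adjusted p = 0.00112; 0.0201 with an estimated correlation). Salicylate response markers rose in 3 of 3 cases (3 adjusted over the list alone), with UGT76B1 (AT3G11340), a glucosyltransferase that dampens salicylate responses, up 56.8-fold (adjusted p of the list = 0.00142, and adjusted p = 0.14 with an estimated correlation). In the list of defence genes that need jasmonate and ethylene, 3 of 5 rose (3 adjusted over the list alone): the plant defensin genes LCR67 (AT1G75830) at least 44.6-fold, PDF1.2b (AT2G26020) 6.58-fold and PDF1.2 (AT5G44420) 5.46-fold (adjusted p = 0.00142; adjusted p = 0.0838 with an estimated correlation). From the list of jasmonate repressors and jasmonate breakdown, 2 of 4 members rose (2 adjusted over the list alone), including the jasmonate oxygenase gene AT5G05600 by 8.77-fold; the list had adjusted p = 0.0107, and adjusted p = 0.191 with an estimated correlation. OPCL1 (AT1G20510), a gene of jasmonate synthesis, rose 3.26-fold. Without replicate 3 of inoculated Col-0 the rises of PUB23, UGT76B1 and LCR67 came to 157-fold, 92.7-fold and at least 76.4-fold, that of PUB23 without replicate 1 to 46.6-fold, and that of AT5G05600 without replicate 2 of mock Col-0 to 5.83-fold.

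The 5 lists named next passed at 9 h in camera with a preset correlation and missed the threshold with an estimated one. Calmodulin-like genes rose in 4 of 7 cases and 3 did not pass, with CML38 (AT1G76650) up 24.0-fold, CML37 (AT5G42380) up at least 21-fold and CML41 (AT3G50770) up 12.9-fold (adjusted p = 0.00162; adjusted p = 0.0593 with an estimated correlation). Of 47 UDP-glycosyltransferase genes 11 rose, 3 fell and 33 did not pass (adjusted p = 0.00806; adjusted p = 0.182 with an estimated correlation); UGT73B5 (AT2G15480) rose 14.4-fold. Single members of other lists rose as well: CCR2 (AT1G80820), a lignin pathway gene, 65.2-fold, WRKY6 (AT1G62300), a regulator of leaf senescence, 18.0-fold, ARL (AT2G44080) 15.9-fold, AT2G04400, of tryptophan synthesis, 9.42-fold, the glutathione transferase gene GSTU25 (AT1G17180) at least 7.00-fold, and BZIP60 (AT1G42990), of the endoplasmic reticulum stress response, 5.23-fold. Replicate 3 of inoculated Col-0 lowered these rises: without it they were 46.2-fold (CML38), at least 36.7-fold (CML37), 24.0-fold (CML41), 32.0-fold (UGT73B5), 102-fold (CCR2), 27.8-fold (WRKY6) and 27.3-fold (ARL). Without replicate 1 they were 15.6-fold (CML38), 7.76-fold (CML41), 8.53-fold (UGT73B5) and 10.5-fold (ARL), and without replicate 1 of mock Col-0 19.5-fold (CML41). Without experiment 3, GSTU25 no longer passed (2.54 log2 units, adjusted p = 0.127). AT2G31790, of aliphatic glucosinolate synthesis, fell 2.44-fold. In tetrapyrrole and chlorophyll synthesis 6 of 13 genes fell and 7 did not pass, for instance LIL3:1 (AT4G17600) by 2.29-fold and CHLI2 (AT5G45930) by 2.11-fold (adjusted p = 0.00162; adjusted p = 0.191 with an estimated correlation). Photosynthesis genes fell in 2 of 7 cases (2 adjusted over the list alone), namely the Calvin cycle genes SBPASE (AT3G55800; 2.13-fold) and PRK (AT1G32060; 1.96-fold); the list had adjusted p = 0.036, and adjusted p = 0.407 with an estimated correlation. Left without replicate 1 of inoculated Col-0 or replicate 3 of mock Col-0, the photosynthesis list did not pass in camera (adjusted p = 0.211 and 0.0853). Nor did it pass with the low-value filter (0.0783), quantile renormalisation (0.103), the experiment as a block (0.0587) or only the arrays compared (0.0573). Of 69 chloroplast-encoded genes 2 fell and 67 did not pass (camera adjusted p = 0.00162; adjusted p = 0.605 with an estimated correlation; fry adjusted p = 0.0832).

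In all, 2873 probe sets passed at 9 h, 1332 higher and 1541 lower after inoculation (1312 and 1225 with median centring); with a 2-fold minimum these numbers were 1107 and 781. With the experiment as a block 4705 passed. When only the 6 arrays compared entered the fit 320 passed, and 24 of the 34 genes named for this comparison missed the threshold.

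At 24 h the same question was put to 2 inoculated and 3 mock Col-0 arrays. OSM34 (AT4G11650), an osmotin-like antifungal protein gene, rose 1040-fold (log2 difference 10.02 ± 0.62 SE, adjusted p = 1.53e-09), from 2.39 ± 0.12 (SD, n = 3) to 12.41 ± 0.26 (SD, n = 2). AT4G16260, a beta-1,3-glucanase gene, rose 966-fold, and the peroxidase genes Prx37 and AT2G37130 rose 307-fold and 185-fold. The defensin genes PDF1.2, PDF1.2b and LCR67 rose 499-fold, 289-fold and at least 211-fold, which together with OSM34 made 4 of 5 measured genes of the jasmonate and ethylene defence list (4 adjusted over the list alone; adjusted p = 2.38e-10, and 0.0018 with an estimated correlation). Of 4 jasmonate repressor and breakdown genes 3 rose (3 adjusted over the list alone; adjusted p = 4.89e-06, and 0.0306 with an estimated correlation): the jasmonate oxygenase genes AT2G38240, JRG21 (AT3G55970) and AT5G05600, by 181-fold, at least 143-fold and 50.4-fold. In the wider group of jasmonate metabolism and regulators 6 of 10 rose and 4 did not pass, OPCL1 by 3.96-fold (adjusted p = 2.89e-07, and 0.0306 with an estimated correlation). Without replicate 1 of mock Col-0 the rises of AT4G16260 and AT5G05600 came to 1610-fold and 76.3-fold. PDF1.2 in inoculated Col-0 lay near the highest value of any probe set on these 2 arrays (14.88 and 14.94). Its differences from lower groups at 24 h may therefore be understated, which was not tested.

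From the pattern-triggered immunity list 4 of 5 rose (4 adjusted over the list alone), among them PUB23 by 14.1-fold, the kinase gene BIK1 (AT2G39660) by 5.04-fold and PUB24 by 3.86-fold (adjusted p = 0.000165, and 0.0492 with an estimated correlation). One salicylate response marker of 3 rose (1 adjusted over the list alone) and the list did not pass (adjusted p = 0.0943); it passed with median centring (adjusted p = 0.0254) and without replicate 1 of mock Col-0 (0.012), but not with the low-value filter (0.186), quantile renormalisation (0.114) or the experiment as a block (0.163). UDP-glycosyltransferase genes rose in 9 of 47 cases, 1 fell and 37 did not pass (adjusted p = 0.0004, and 0.0492 with an estimated correlation), with UGT71C3 (AT1G07260) up 53.1-fold and UGT73B5 up at least 23.9-fold. The cytochrome P450 genes CYP71B22 (AT3G26200) and CYP71B6 (AT2G24180) rose 82.5-fold (50.7-fold without replicate 1 of mock Col-0) and 16.5-fold, GSTU25 rose 17.3-fold, WRKY6 rose 14.4-fold, AT2G04400 rose 8.72-fold, and the clock gene GI (AT1G22770) rose 3.70-fold.

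Among 27 expansin and xyloglucan hydrolase genes 7 fell at 24 h and 20 did not pass, EXPA8 (AT2G40610) by 31.1-fold, or 58.0-fold without replicate 1 of mock Col-0 (list adjusted p = 0.00475; adjusted p = 0.283 with an estimated correlation). Tetrapyrrole and chlorophyll synthesis genes fell in 6 of 13 cases and 7 did not pass, with PORB (AT4G27440) down 5.73-fold, CHLI2 down 4.08-fold and HEME1 (AT3G14930) down 3.39-fold (adjusted p = 4.89e-06, and 0.0492 with an estimated correlation). AT5G48490, a lipid transfer protein gene, fell 31.2-fold, the thionin gene THI2.2 (AT5G36910) fell 16.8-fold (26.5-fold and 10.6-fold without replicates 1 and 2 of inoculated Col-0), the chalcone isomerase-like gene CHIL (AT5G05270) fell at least 17.0-fold, and the guard cell marker AT1G22690 fell 3.40-fold. AT5G55450, a lipid transfer protein gene, fell 26.1-fold (log2 difference -4.70 ± 0.99 SE, adjusted p = 0.00245), but without replicate 2 of inoculated Col-0 the difference was -3.90 and did not pass (adjusted p = 0.0659). Without replicate 1 of inoculated Col-0 it fell 45.6-fold, and without replicate 1 of mock Col-0 15.4-fold.

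Altogether 2997 probe sets passed at 24 h, 1525 higher and 1472 lower after inoculation (1194 and 1078 with a 2-fold minimum, 1219 and 1566 with median centring). With the experiment as a block 4256 passed, against 1381 without replicate 1 and 1724 without replicate 2 of inoculated Col-0; each of these refits leaves 1 array in that group, assumed to vary like the others. When only the 5 arrays compared entered the fit, 8 of the 31 genes named for this comparison missed the threshold.

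**Figure D2:**
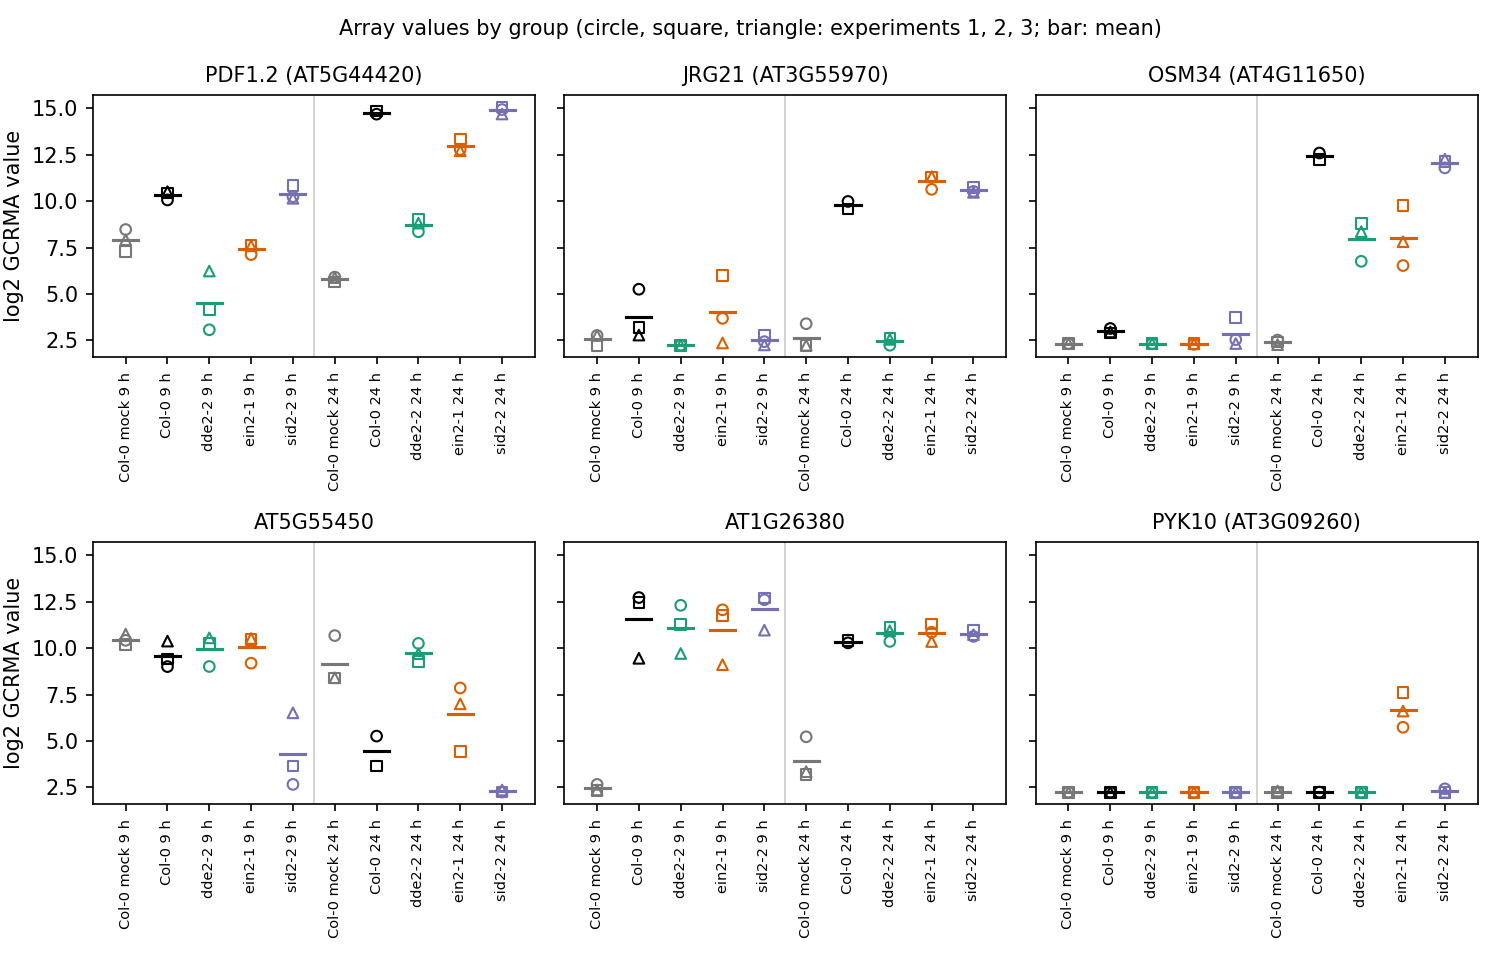
Log2 signal of 6 genes on every array (vertical axes), by group (horizontal axes, mock Col-0 first, then inoculated Col-0, then inoculated mutants in the order dde2-2, ein2-1, sid2-2, at 9 h and then 24 h), with a symbol per experiment and a bar at the mean. PDF1.2 reached 14.77 in inoculated Col-0 and 8.73 in dde2-2 at 24 h, and PYK10 stood at 6.66 in ein2-1 at 24 h and no higher than 2.29 on average in any other group.

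Which responses need jasmonate was asked with dde2-2. At 9 h (n = 3 each) the jasmonate oxygenase gene AT5G05600 was 76.3-fold lower in dde2-2 than in Col-0 (log2 difference -6.25 ± 0.54 SE, adjusted p = 1.2e-06), PDF1.2 was 57.9-fold lower and PDF1.2b was 45.6-fold lower. Without replicate 3 of dde2-2 the defensin genes were 106-fold and 72.5-fold lower, and without replicate 1 PDF1.2 was 35.4-fold lower. PDF1.2 stood at 4.48 ± 1.61 in dde2-2 and 10.34 ± 0.24 in Col-0 (SD, n = 3 each), and at 7.89 ± 0.60 in mock Col-0. AT3G51450, which encodes a strictosidine synthase-like protein, and UGT71C3 were lower 16.1-fold and 15.0-fold. Higher in dde2-2 were QQS (AT3G30720), a gene that affects leaf starch, 6.46-fold, and AT1G14780, 2.93-fold. Of the jasmonate and ethylene defence list 3 of 5 were lower (3 adjusted over the list alone; adjusted p = 1.13e-10, and 0.00151 with an estimated correlation). The jasmonate repressor and breakdown list had 2 of 4 lower (3 adjusted over the list alone; adjusted p = 9.3e-08, and 0.00845 with an estimated correlation), and the jasmonate metabolism and regulator group 3 of 10 lower and 7 not past the threshold (adjusted p = 1.4e-07, and 0.0284 with an estimated correlation). GRX480 (AT1G28480), a glutaredoxin gene on the list of salicylate response markers, differed by -2.80 ± 0.73 from Col-0 and did not pass (adjusted p = 0.113). It passed with the experiment as a random block (adjusted p = 0.039) and not as a fixed block (0.0564), nor without experiment 3 (0.328), while dde2-2 lay 21.1-fold below ein2-1 (adjusted p = 0.00322), a difference that did not pass without experiment 3 (-4.43 log2 units, adjusted p = 0.0784).

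Across all probe sets 105 passed between dde2-2 and Col-0 at 9 h, 23 higher and 82 lower in dde2-2, and 210 passed with the experiment as a block. The count was 42 without replicate 1 and 330 without replicate 3 of Col-0, 68 without replicate 3 of dde2-2, 396 without all of experiment 3, and 3 with only the 6 arrays compared, where all 7 genes called by name missed the threshold.

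After 24 h (3 dde2-2 arrays, 2 of Col-0) the jasmonate oxygenase genes AT2G38240, JRG21 and AT5G05600 were 197-fold, 159-fold and 42.6-fold lower in dde2-2 (log2 differences -7.62 ± 0.86, -7.31 ± 0.72 and -5.41 ± 0.60 SE; adjusted p = 9.76e-06, 1.75e-06 and 8.67e-06). They were the 3 of 4 measured genes of the jasmonate repressor and breakdown list that were lower (3 adjusted over the list alone; adjusted p = 2.96e-10, and 0.0022 with an estimated correlation). PDF1.2, PDF1.2b and OSM34 were lower 65.8-fold, 28.6-fold and 21.8-fold (OSM34 14.3-fold without replicate 1 of dde2-2), and 4 of the 5 jasmonate and ethylene defence genes were lower in all (4 adjusted over the list alone; adjusted p = 4.22e-12, and 0.000722 with an estimated correlation). Jasmonate metabolism and regulator genes were lower in 5 of 10 cases (adjusted p = 1.13e-11, and 0.00373 with an estimated correlation). AT3G23550, which encodes a MATE transporter, was 88.8-fold lower, UGT71C3 50.7-fold, UGT85A4 (AT1G78270) 9.67-fold, and SWEET17 (AT4G15920), a fructose transporter gene, 8.34-fold.

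Other genes were higher in dde2-2 at 24 h. AT5G55450 was 39.3-fold higher (log2 difference 5.30 ± 0.99 SE, adjusted p = 0.00272), a call lost without replicate 2 of Col-0 (4.49, adjusted p = 0.0939) and 68.8-fold without replicate 1. The peroxidase gene PRX52 (AT5G05340) was 27.3-fold higher, AT3G22620 26.5-fold, and the glucosyltransferase gene UGT76D1 (AT2G26480), which acts on breakdown products of salicylate, at least 6.98-fold. Among 10 autophagy genes of the ATG8 family and ATG3, 1 passed as higher, APG8A (AT4G21980) by 2.40-fold, and 9 did not pass; camera gave adjusted p = 0.000108 for the group, and 0.0178 with an estimated correlation.

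In total 822 probe sets passed between dde2-2 and Col-0 at 24 h, 360 higher and 462 lower in dde2-2 (345 and 331 with median centring); with the experiment as a block the count was 1417, and with only the 5 arrays compared it was 219, where 8 of the 15 named genes missed the threshold. It was 403 without replicate 1 and 354 without replicate 2 of Col-0, and 531 without replicate 2 and 520 without replicate 3 of dde2-2.

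Ethylene signalling was addressed with ein2-1. At 9 h (n = 3 each) PDF1.2b was 7.55-fold lower in ein2-1 than in Col-0 (log2 difference -2.92 ± 0.47 SE, adjusted p = 0.00822) and PDF1.2 was 7.44-fold lower (-2.90 ± 0.49, adjusted p = 0.00971). PDF1.2 did not pass without replicate 1 of ein2-1 (-2.73, adjusted p = 0.0534), nor PDF1.2b without experiment 3 (-2.69, adjusted p = 0.0533). They were the 2 of 5 jasmonate and ethylene defence genes called (3 lower adjusted over the list alone; adjusted p = 1.5e-07, and 0.00955 with an estimated correlation). PDF1.2 was lower still in dde2-2, by 7.77-fold against ein2-1 (adjusted p = 0.0029; 4.76-fold and 14.3-fold without replicates 1 and 3 of dde2-2). AT3G46280 was 13-fold lower in ein2-1, UGT71C3 6.13-fold lower, and the formate dehydrogenase gene FDH (AT5G14780) 2.97-fold lower, while AT3G19030 was 5.28-fold higher. AT5G05600, which was low in dde2-2, stood at 8.85 in ein2-1 and 9.10 in Col-0, and dde2-2 lay 64.3-fold below ein2-1 (adjusted p = 1.96e-06). AT3G46280 was 15.8-fold higher in dde2-2 than in ein2-1 (adjusted p = 0.000622). ARL, from the ethylene response list, differed by -2.62 ± 0.56 from Col-0 (adjusted p = 0.0669). It passed with the experiment as a random block (adjusted p = 0.0279), with the low-value filter (0.026), with median centring (0.0257), without replicate 3 of Col-0 (-3.40, 0.00165) and without experiment 3 (-3.06, 0.00497). It did not pass with the experiment as a fixed block (0.0512), with quantile renormalisation (0.0942) or without replicate 1 of Col-0 (-2.03, 0.252). ARL was 9.90-fold lower in ein2-1 than in sid2-2 (adjusted p = 0.00257).

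Between ein2-1 and Col-0 at 9 h 40 probe sets passed, 12 higher and 28 lower, and 72 with the experiment as a block. The count was 21 without replicate 2 of ein2-1, 115 without replicate 3 of Col-0 and 82 without all of experiment 3; with only the 6 arrays compared limma called 0 (433 at an unadjusted p under 0.05), so all 6 genes called by name missed the threshold.

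At 24 h (3 ein2-1 arrays, 2 of Col-0) the beta-glucosidase gene PYK10 (AT3G09260), whose product fills endoplasmic reticulum bodies, was at least 21.5-fold higher in ein2-1 (log2 difference 4.42 ± 0.28 SE, adjusted p = 8.9e-09), and at least 20.6-fold higher than in sid2-2 (adjusted p = 9.54e-10), since arrays of both lie at the floor. The glucomannan synthase gene CSLA01 (AT4G16590) was at least 9.33-fold higher and the jacalin-like lectin gene JAL33 (AT3G16450) at least 4.64-fold higher than in Col-0, where both lay at a shared low value (at least 14.4-fold for CSLA01 without replicate 2 and 7.61-fold for JAL33 without replicate 1 of ein2-1). The errors for PYK10 and JAL33 come mostly from arrays at or near a shared low value. They measure little of the spread in ein2-1 at 24 h, where the SDs were 0.94 and 1.24 (n = 3). With only the arrays compared neither gene passed in limma (adjusted p = 0.48 for PYK10 and 0.972 for JAL33). Lower in ein2-1 were OSM34, 20.7-fold (-4.37 ± 0.62, adjusted p = 0.000623; 12.3-fold and 37.8-fold without replicates 1 and 2 of ein2-1), and UGT74F1 (AT2G43840), a salicylate glucosyltransferase gene, at least 3.97-fold. Without experiment 3 the log2 differences changed little but the calls were lost for CSLA01 (2.84, main 3.22; adjusted p = 0.083), JAL33 (1.86, main 2.21; 0.208) and OSM34 (-4.26; 0.111), as was that of OSM34 between ein2-1 and sid2-2 (main difference -4.03, adjusted p = 0.000244; without experiment 3 -3.82, 0.0708; without replicates 1 and 2 of ein2-1 9.67-fold and 29.8-fold lower). OSM34 was the only member called of the 5 jasmonate and ethylene defence genes (2 lower adjusted over the list alone); the list had camera adjusted p = 0.000428, adjusted p = 0.123 with an estimated correlation, and fry adjusted p = 0.0729. PDF1.2 differed by -1.82 ± 0.55 (adjusted p = 0.274, called with either array weighting only), JRG21 by 1.31 ± 0.72 and AT2G38240 by 0.80 ± 0.86 (adjusted p = 1 for both), and ARL by -1.82 ± 0.62 (adjusted p = 0.437; -2.22, adjusted p = 0.0353 without experiment 3; 0.384 and 0.313 with the experiment as a fixed and random block).

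The jasmonate- and ethylene-related mutants were also set against each other at 24 h. JRG21 was 393-fold lower in dde2-2 than in ein2-1 (log2 difference -8.62 ± 0.64 SE, adjusted p = 2e-08) and PDF1.2 18.6-fold lower (adjusted p = 8e-06). The jacalin-like lectin genes JAL34 (AT3G16460) and JAL23 (AT2G39330) were 49.9-fold and at least 75.7-fold lower in dde2-2 (adjusted p = 5.58e-08 and 1.49e-05; JAL23 at least 114-fold without replicate 3 of ein2-1). QQS was 10.2-fold higher in dde2-2 at 24 h (adjusted p = 5.55e-07) and 7.91-fold higher at 9 h (adjusted p = 2.18e-05).

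Relative to Col-0, 113 probe sets passed in ein2-1 at 24 h, 60 higher and 53 lower; 132 passed with the experiment as a block. The count was 61 without experiment 3 and 9 with only the 5 arrays compared, where all 5 genes called by name missed the threshold.

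Salicylate-dependent genes were sought with sid2-2. At 9 h (n = 3 each) AT5G55450 was 40.2-fold lower in sid2-2 than in Col-0 (log2 difference -5.33 ± 0.88 SE, adjusted p = 0.00455), and 87.5-fold and 23.0-fold lower without replicates 3 and 1 of sid2-2. AT5G03350, a legume lectin-like gene, was 29.8-fold lower (-4.90 ± 0.56, adjusted p = 7.79e-05), AT3G48080, a relative of EDS1, 12.7-fold lower, and AT1G76960 11.2-fold lower, the last not past the threshold without experiment 3 (-3.61, adjusted p = 0.0936). AT3G26630 was 2.12-fold higher. PDF1.2 differed by 0.07 ± 0.49 (adjusted p = 1), and this difference turned to -0.07 without replicate 1 of Col-0 and to -0.14 without replicate 2 of sid2-2. None of the 3 salicylate response markers passed over all probe sets in limma, and 2 were lower adjusted over the list alone; UGT76B1 differed by -3.51 ± 0.85 (adjusted p = 0.0741). UGT76B1 did pass with the experiment as a fixed or random block (adjusted p = 0.00974 and 0.00838), with the low-value filter (0.0353), with median centring (0.0264) and without replicate 3 of Col-0 (-4.21, 0.0424). With quantile renormalisation (0.0651), without experiment 3 (0.101) and without any other array it did not. Camera called that list lower (adjusted p = 0.0109), with adjusted p = 0.302 with an estimated correlation, and fry did not (adjusted p = 0.205). Camera also missed the threshold without replicate 1 of Col-0 (adjusted p = 0.225) and without replicate 3 of sid2-2 (0.104).

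Some of these genes were also compared between mutants. AT5G55450 was 51.0-fold higher in dde2-2 than in sid2-2 at 9 h (adjusted p = 0.000971; 111-fold and 29.1-fold without replicates 3 and 1 of sid2-2) and 177-fold higher at 24 h (adjusted p = 8.25e-06). AT5G03350 was 18.3-fold higher in dde2-2 at 9 h (adjusted p = 0.000211; 29.8-fold without replicate 1 of dde2-2) and 47.8-fold higher at 24 h (adjusted p = 7.95e-07), and in ein2-1 it was 49.7-fold and 47.1-fold higher than in sid2-2 (adjusted p = 1.08e-05 and 4.3e-06). AT3G48080 was 12.3-fold higher in dde2-2 at 9 h (adjusted p = 0.00234). PDF1.2 went the other way: it was 60.8-fold and 72.2-fold lower in dde2-2 than in sid2-2 at 9 h and 24 h (adjusted p = 7.63e-07 and 4.09e-08; at 9 h 37.2-fold and 111-fold without replicates 1 and 3 of dde2-2), and 7.82-fold lower in ein2-1 than in sid2-2 at 9 h (adjusted p = 0.00211). JRG21 was 276-fold lower in dde2-2 than in sid2-2 at 24 h (adjusted p = 4.09e-08).

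For sid2-2 against Col-0 at 9 h 126 probe sets passed, 32 higher and 94 lower, and 287 with the experiment as a block. The count was 55 without replicate 1 of Col-0 and 74 without replicate 2 of sid2-2; with only the 6 arrays compared limma called 0 (717 at an unadjusted p under 0.05), so all 5 genes called by name missed the threshold.

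By 24 h (3 sid2-2 arrays, 2 of Col-0) AT1G19960 was 16.9-fold lower in sid2-2 (log2 difference -4.08 ± 0.67 SE, adjusted p = 0.00799), a call lost without replicate 1 of Col-0 (-3.95, adjusted p = 0.0879); it was 10.9-fold lower without replicate 2 of sid2-2. AT2G41090, a calcium-binding protein gene, was 2.53-fold lower and AT3G22240 2.1-fold lower. SIS (AT5G02020) was 2.62-fold higher and UGT74F1 2.5-fold higher. PDF1.2 differed by 0.13 ± 0.55 (adjusted p = 1). In Col-0 it already lay near the highest values on those arrays (14.88 and 14.94), so a higher level in sid2-2 could have been missed. In this comparison 31 probe sets passed, 9 higher and 22 lower, and 45 with the experiment as a block. The count was 54 without replicate 1 and 58 without replicate 2 of Col-0, and 16 with only the 5 arrays compared, where all 5 genes called by name missed the threshold.

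How much of the wild-type response each mutant showed was measured in held-out experiments. Probe sets were chosen for a difference of at least 2-fold in the same direction in every other experiment, and the mutant's distance from mock Col-0 was divided by that of inoculated Col-0 in the experiment left out. At 9 h the share was 76.9% ± 5.8 in dde2-2, 84.2% ± 6.1 in ein2-1 and 102.5% ± 19.3 in sid2-2 (SD, n = 3 experiments). At 24 h it was 84.5% ± 9.1 in dde2-2, 103.7% ± 10.1 in ein2-1 and 108.5% ± 8.2 in sid2-2 (SD, n = 2 experiments). On induced probe sets at 9 h the shares were 80.9% ± 4.5, 87.2% ± 4.0 and 108.3% ± 21.5 and on reduced ones 63.5% ± 14.8, 73.8% ± 16.7 and 80.9% ± 19.9, in the same order. At 24 h they were 88.2% ± 9.5, 109.4% ± 10.3 and 106.4% ± 6.0 on induced and 79.0% ± 8.1, 95.1% ± 9.4 and 111.6% ± 11.7 on reduced ones. No test was made of these shares, and a difference in the mutants before infection would enter them. The choice of probe sets needed agreement between experiments at 9 h (1328 to 2892 probe sets). At 24 h it rested on a single experiment (3245 to 4275), so shares at 9 h and 24 h are not directly comparable. With 2 arrays of inoculated Col-0 at 24 h, the resemblance between arrays of one number could not decide whether their pairing holds. The pairing behind the 24 h shares is therefore uncertain.

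**Figure D3:**
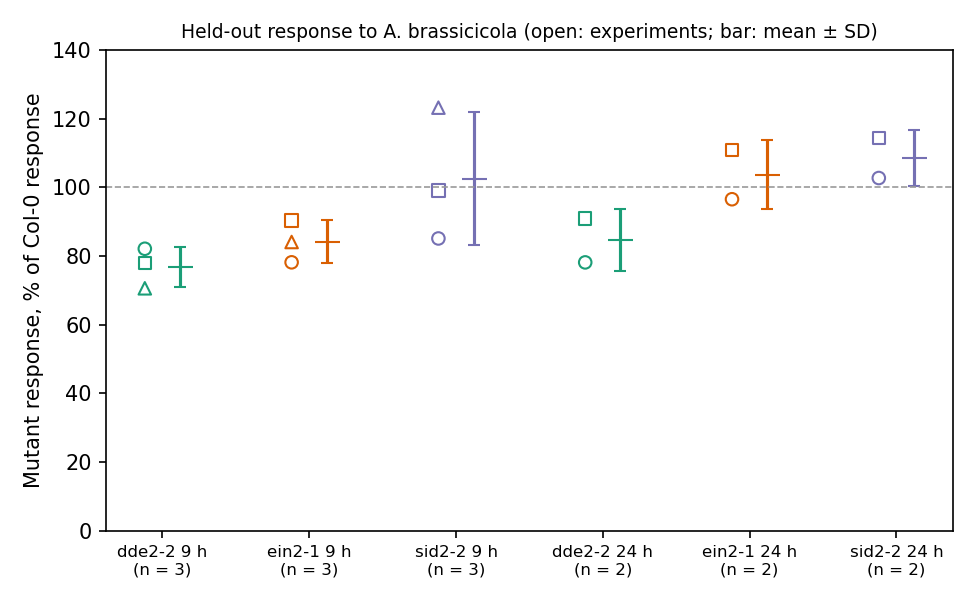
Response of each mutant as a percentage of the Col-0 response (vertical axis, from 0) at 9 h and 24 h (horizontal axis), with one open symbol per experiment left out and a bar at the mean ± SD. The lowest mean is that of dde2-2 at 9 h, 76.9%, and the dashed line marks the Col-0 response.

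Time without the fungus was examined in mock Col-0 (n = 3 each), where the 24 h and 9 h leaves also differ in clock hour (10 and 19) and in hours at saturating humidity. Lower at 24 h were AT4G30650 by 361-fold (log2 difference -8.50 ± 0.38 SE, adjusted p = 1.46e-12), COR27 (AT5G42900) by 106-fold and COR15B (AT2G42530) by 67.4-fold. AT1G07050 and AT1G56300 were 146-fold and 126-fold lower. All 3 measured genes of the abscisic acid and water deficit list were lower (3 adjusted over the list alone): COR15A (AT2G42540) by 13.1-fold, LTI30 (AT3G50970) by at least 5.34-fold and COR47 (AT1G20440) by 2.65-fold (camera adjusted p = 0.00845; adjusted p = 0.145 with an estimated correlation). The clock gene GI was 19.8-fold lower, the beta-glucosidase gene BGLU44 (AT3G18080) 29.3-fold, PORB 16.8-fold, the autophagy gene ATG8D (AT2G05630) 6.12-fold, and PDF1.2 and PDF1.2b 4.23-fold and 4.54-fold. Higher at 24 h were the cysteine protease gene AT2G27420 by 128-fold, AT1G64500 by 105-fold, AT5G48490 by 63.7-fold, the phytochrome signalling gene AFR (AT2G24540) by 35.8-fold, the trichome gene TRY (AT5G53200) by 33.7-fold (50.7-fold without replicate 3 at 9 h), THI2.2 by 24.9-fold and the lignin gene HCT (AT5G48930) by 3.07-fold. Sugar transporter genes of the SWEET family were higher in 5 of 14 cases and 9 did not pass, with SWEET2 (AT3G14770) at 28.7-fold and SWEET13 (AT5G50800) at 3.29-fold. The SWEET group did not pass in camera (adjusted p = 0.0713; adjusted p = 0.562 with an estimated correlation) and passed in fry (adjusted p = 0.0046); camera passed with the low-value filter (adjusted p = 0.0218) and without replicate 1 of mock Col-0 at 24 h (0.0244) or replicate 3 at 9 h (0.028), but not with quantile renormalisation (0.163), median centring (0.166) or the experiment as a block (0.0929).

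Over all probe sets 2633 passed between the mock times, 1313 higher and 1320 lower at 24 h (1177 and 1088 with median centring), and 4125 passed with the experiment as a block. With only the 6 arrays compared 1348 passed, and 4 of the 23 named genes missed the threshold.

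Whether effects differed between the times was tested directly. The infection response of Col-0 differed for 712 probe sets, 454 with a larger value at 24 h and 258 with a smaller one; with median centring these were 265 and 275, so the majority depends on the centring. OSM34 gained 9.35 ± 0.83 log2 units between the times (SE, adjusted p = 1.27e-06) and PDF1.2 gained 6.51 ± 0.73 (adjusted p = 2.32e-05), whereas AT2G04070 lost ground (-6.13 ± 0.95, adjusted p = 0.000718). For dde2-2 against Col-0 the count was 232 (88 larger, 144 smaller; 83 and 60 with median centring), with JRG21 at -5.80 ± 0.96 (adjusted p = 0.00303). For ein2-1 it was 24 (15 and 9; 17 and 31 without replicate 1 and 10 and 37 without replicate 2 of inoculated Col-0 at 24 h), with PYK10 at 4.42 ± 0.37 (adjusted p = 1.8e-06), a size limited by the floor, where all its 9 h arrays lay. The error for PYK10 comes mostly from arrays at that floor and measures little of its spread in ein2-1 at 24 h. For sid2-2 the count was 2 (1 and 1), neither with one gene in the tables used. With the experiment as a block these 4 counts were 1319, 460, 28 and 6.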

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

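The test of matched random sets on the dde2-2 and Col-0 difference, the GAPDH test of RNA quality and the comparison of experiments on common lists were chosen after the results they measure were seen. Every result named first in this part stands out because an effect differed between 9 h and 24 h by a test of that difference in limma. In Col-0 the response to the fungus differed between the times for 712 probe sets (346 without replicate 1 and 375 without replicate 2 of inoculated Col-0 at 24 h). The signed response at 24 h lay above that at 9 h for OSM34 (9.35 log2 units), PDF1.2 (6.51), JRG21 (6.01), AT2G37130 (5.54), PDF1.2b (5.46), AT2G38240 (4.45), AT4G16260 (4.41), AT3G28270 (2.78) and GI (2.15); AT3G28270 fell at 9 h and differed by 0.14 at 24 h. It lay below that at 9 h for BZIP60 (-1.44), AT1G22690 (-1.74), PUB22 (-1.94), PORB (-1.98), CHIL (-4.12), THI2.2 (-4.17), AT2G23270 (-4.66), AT5G48490 (-4.68), UGT76B1 (-4.88), CCR2 (-4.96) and AT2G04070 (-6.13), where PORB differed by -0.54 at 9 h and -2.52 at 24 h. A group at the floor or at a shared low value enters the sizes for JRG21, PUB22, CHIL and CCR2, which are therefore not exact.

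The difference between dde2-2 and Col-0 changed with time for 232 probe sets: upward for PRX52 (5.59), AT3G22620 (3.97), UGT76D1 (2.72) and APG8A (1.52), and downward for UGT85A4 (-2.83), OSM34 (-3.77), AT3G23550 (-4.38) and JRG21 (-5.80). Sizes for UGT76D1 and JRG21 here, and for the 3 genes named next in ein2-1, are likewise limited by the floor. Left-out arrays moved that count to 401 (dde2-2 at 24 h replicate 1), 154 (dde2-2 at 24 h replicate 3), 142 and 131 (dde2-2 at 9 h replicates 2 and 3), 133 (Col-0 at 9 h replicate 1) and 112 (Col-0 at 24 h replicate 2). For ein2-1 the count was 24, with PYK10 (4.42) and CSLA01 (3.22) upward and UGT74F1 (-1.99) downward; it was 48 (17 higher, 31 lower) and 47 (10 and 37) without replicates 1 and 2 of Col-0 at 24 h, 42 without replicate 3 of Col-0 at 9 h and 39 without replicate 2 of ein2-1 at 24 h. For sid2-2 it was 2, and between 6 and 27 without any 1 of 9 arrays: 27 and 26 (Col-0 at 24 h replicates 1 and 2), 10 and 6 (sid2-2 at 24 h replicates 3 and 1), 9 and 7 (Col-0 at 9 h replicates 2 and 3), and 8, 7 and 8 (sid2-2 at 9 h replicates 1, 2 and 3).

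Salicylate-dependent probe sets were high in dde2-2 late in infection. The 94 probe sets lower in sid2-2 than in Col-0 at 9 h had a median 1.07 log2 units higher in dde2-2 than in Col-0 at 24 h (random sets -0.16 to 0.07), with 87 of 94 higher, 36 called higher and 1 called lower. A candidate explanation is that such genes are held down at 24 h in plants that make jasmonate, and it stays a hypothesis because it was found and tested on the same arrays. Against the absence of experiment 3 from Col-0 as the cause stands a median of 1.15 from experiments 1 and 2 alone (0.95 and 1.36 in each), if the replicate numbers name the experiments. Against low values on the 2 Col-0 arrays alone stands a median of 0.96 between dde2-2 and ein2-1 at 24 h (random sets -0.05 to 0.13). An effect of the dde2-2 mutation in uninfected leaves stays open, since no mutant was mock inoculated.

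The response to the fungus at 9 h was weaker in experiment 3, at 48.8% of that in experiment 1 and 53.9% of that in experiment 2, each on one list of probe sets chosen in the third experiment. Degraded RNA could raise the GAPDH 3' minus 5' difference, but at 9 h this was 0.52 log2 units lower in experiment 3 (difference -0.52; 1.101 ± 0.208, SD, 5 arrays, against 1.616 ± 0.286, 10 arrays), which argues against it. A smaller contrast on all arrays of experiment 3 stays open: the mock difference between the times there was 75.7% of that in experiment 1 and 66.1% of that in experiment 2 on such lists (mean 70.9%), between the bounds of 60% and 80% set for and against it. That mock difference and the weaker response both subtract the same array, mock Col-0 at 9 h of experiment 3. A deviation of that array could lower both, so the comparison cannot separate it from a smaller contrast on all arrays. Slower infection in experiment 3 also stays open and was not tested.

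Splits of the 6 arrays of each comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. For inoculated against mock Col-0 at 9 h 1 split, the real one, gave as many probe sets (2873; highest other 17), for ein2-1 against Col-0 at 9 h 1 (40; highest other 12), and for mock Col-0 at 24 h against 9 h 1 (2633; highest other 75). For dde2-2 at 9 h 2 splits gave 105 or more: the real one and one with 1866, which sets replicates 1 of both genotypes and replicate 2 of Col-0 against the rest, so the 6 arrays hold a structure larger than the genotype difference. For sid2-2 at 9 h 2 splits gave 126 or more, the second (145) setting replicate 1 of both genotypes and replicate 2 of sid2-2 against the rest. Both of these put experiment 1 against experiment 3, and with the experiment as a block the counts were 210 for dde2-2 and 287 for sid2-2. The 4 splits that part every pair of one experiment, as the real one does, gave at most 5, 2, 1, 2 and 22 in the other 3, in the order Col-0 at 9 h, dde2-2, ein2-1, sid2-2 and mock times.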

How the results depend on the processing

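Leaving out experiment 3, leaving out probe sets at the floor on every array, and array weights by the gene-by-gene method were chosen after seeing the data; the other alternatives were planned. Of 164 gene results from comparisons of 2 groups 155 passed. Gene differences between the times, and gene results given only under other observations, are not among the 164. None of the 147 calls that the low-value filter leaves ended there (8 lost their probe set), and none of 155 with quantile renormalisation, median centring, no intensity trend, robust variances, either array weighting or either block. A call ended for 1 with a 2-fold minimum (PRK), for 8 without experiment 3, for 4 without a single array (few by choice, since genes resting on one array were mostly not named) and for 87 with only the arrays compared, which leaves fewer arrays to estimate the spread. The losses with only the arrays compared did not follow the number of arrays alone. Between dde2-2 and ein2-1, with 3 arrays each, 5 of 5 calls ended at 9 h and 0 of 5 at 24 h. For infection 24 of 34 ended at 9 h and 8 of 31 at 24 h. The main fit gives all groups one spread, so its errors may be too small where arrays vary more, which was not tested. Calls were gained in some settings by 5 gene results that had none (ARL in ein2-1 at both times, GRX480, PDF1.2 and UGT76B1) and by 2 lists (salicylate markers at 24 h and SWEET transporters). For 40 of the 164 the fold moved over 1.5 times without a single array. PDF1.2 in sid2-2 at 9 h, not called and 0.07 with all arrays, was -0.07 without replicate 1 of Col-0, -0.14 without replicate 2 of sid2-2 and 0.20 without replicate 3 of sid2-2. Of 30 list results 28 passed: photosynthesis at 9 h was lost with the low-value filter, quantile renormalisation, the experiment as a block, only the arrays compared, and without replicate 1 of inoculated or replicate 3 of mock Col-0, and salicylate markers in sid2-2 at 9 h without replicate 1 of Col-0 or replicate 3 of sid2-2. Signal over background limits what can be seen at the floor, where differences are bounds. The cause of the changes in count below was not tested. Fewer arrays or probe sets enter some of them by construction.

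Counts are given in the order inoculated against mock Col-0 at 9 h and 24 h; dde2-2, ein2-1 and sid2-2 against Col-0 at 9 h; the same at 24 h; mock times; and the differences between times for infection, dde2-2, ein2-1 and sid2-2. Default array weights, whose estimation stopped before it converged (weights 0.0957 to 29.8), gave 9096, 6615, 6165, 3688, 2113, 4532, 771, 1054, 7052, 5028, 4500, 1186 and 571; gene-by-gene weights (0.127 to 3.71) gave 6368, 6184, 2540, 750, 721, 4024, 724, 640, 5132, 2959, 2549, 285 and 80. With the experiment as a fixed block the counts that moved over 1.5 times were 4705 (infection, 9 h), 210, 72 and 287 (dde2-2, ein2-1 and sid2-2, 9 h), 1417 (dde2-2, 24 h), 4125 (mock times), and 1319, 460 and 6 (differences for infection, dde2-2 and sid2-2). As a random block it gave 4476 (infection, 9 h), 280, 71 and 293 (mutants, 9 h), 1402 (dde2-2, 24 h), 57 (sid2-2, 24 h), 4005 (mock times) and 1311, 504, 37 and 7 (differences). With only the arrays compared they were 320 (infection, 9 h), 3, 0 and 0 (mutants, 9 h; 433 and 717 for ein2-1 and sid2-2 at an unadjusted p under 0.05 in limma), 219, 9 and 16 (mutants, 24 h), 1348 (mock times) and 347, 67 and 10 (differences for infection, dde2-2 and ein2-1).

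Without experiment 3 the counts that moved were 396 and 82 (dde2-2 and ein2-1, 9 h), 61 (ein2-1, 24 h) and 24 (sid2-2 difference). The low-value filter moved the differences for dde2-2, ein2-1 and sid2-2 to 153, 10 and 1; the sid2-2 difference was 7 with quantile renormalisation, 5 with no trend, 5 with robust variances and 1 with a 2-fold minimum, which also gave 1888 for infection at 9 h. Median centring gave 143 for the dde2-2 difference (83 higher, 60 lower) and shifted the median of all probe sets by -0.14 for infection at 24 h, -0.15 for its difference between times and 0.10 for that of dde2-2; the larger side of the split changed for infection at 9 h (1312 higher, 1225 lower) and 24 h (1219 and 1566), for dde2-2 at 24 h (345 and 331), for the mock times (1177 and 1088), for the infection difference (265 and 275) and for the dde2-2 difference. The share in dde2-2 at 9 h was 83.9% with selection at 4-fold.

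With one array left out the counts ranged from 2069 to 3618 and 1381 to 3697 (infection, 9 h and 24 h), 42 to 330, 21 to 115 and 55 to 186 (dde2-2, ein2-1 and sid2-2, 9 h), 354 to 929, 89 to 137 and 30 to 58 (24 h), 2234 to 3058 (mock times), and 346 to 858, 112 to 401, 21 to 48 and 2 to 27 (differences).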

Other observations

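The genes of the next 2 paragraphs were chosen after their values were seen. Some genes linked with endoplasmic reticulum bodies, compartments that store beta-glucosidases, were looked up in ein2-1 at 24 h. NAI1 (AT2G22770), the regulator of these bodies, stood at 6.34 ± 0.39 in ein2-1 at 24 h, 4.39 ± 0.42 (n = 2) in inoculated Col-0 and 2.95 ± 0.15 in dde2-2 (log2, SD, n = 3 unless given), and dde2-2 lay 10.5-fold below ein2-1 (adjusted p = 3.32e-07). The difference between ein2-1 and Col-0 was 1.95 log2 units (adjusted p = 0.00582). NAI2 (AT3G15950) stood at 5.13 ± 0.87 in ein2-1 and was at least 7.41-fold lower in dde2-2 (adjusted p = 0.0044), but did not pass between ein2-1 and Col-0 (adjusted p = 0.414). JAL34 passed between ein2-1 and Col-0 (adjusted p = 0.021) and JAL23 did not (adjusted p = 0.593). At 9 h JAL34 was already 6.22-fold higher in ein2-1 (adjusted p = 0.0112). No change of this difference with time was detected (-0.14 ± 0.68 log2 units, SE, adjusted p = 1), though its error leaves room for one. JAL34 rose 6.99-fold (adjusted p = 0.000606) and JAL23 rose 13.4-fold (adjusted p = 0.00437) in Col-0 after inoculation at 24 h. PYK10 and JAL33 stood at 6.66 ± 0.94 and 4.46 ± 1.24 in ein2-1 at 24 h, against 2.23 and 2.25 in ein2-1 at 9 h, where all 3 arrays lay at a shared low value. JAL22 (AT2G39310) stayed between 2.23 and 2.26 in every group.

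QQS was high in dde2-2 at both times, at 9.49 ± 0.38 and 9.35 ± 0.46 (SD, n = 3), against 6.79 ± 0.49 (n = 3) and 6.98 ± 0.30 (n = 2) in inoculated Col-0. At 24 h the difference was 5.18-fold (adjusted p = 0.000311). In mock Col-0 it stood at 7.57 ± 0.37 and 7.49 ± 0.26 (n = 3 each).

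The sets of probe sets behind the next values were taken from the 9 h comparisons. The 94 probe sets lower in sid2-2 at 9 h had a median difference from Col-0 of -0.95 log2 units there at 24 h (random sets -0.07 to 0.03; 90 of 94 lower, 13 called lower), and a median of 0.15 in ein2-1 (random sets -0.17 to 0.00). Their median response to the fungus in Col-0 at 24 h was -0.10 (random sets -0.13 to 0.22), and -0.24 in experiments 1 and 2 alone (random sets -0.14 to 0.19). It was -0.62 in experiment 1 and -0.10 in experiment 2, if the replicate numbers name the experiments. The 82 probe sets lower in dde2-2 at 9 h had a median difference of -2.01 in dde2-2 at 24 h, with 43 called lower, and a median response of 2.57 in Col-0 at 24 h, with 65 called higher.

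One hypothesis, that these jasmonate-dependent probe sets might also need EIN2 at 24 h, was tested on the 82. Their median difference between ein2-1 and Col-0 at 24 h was 0.52 log2 units, above the range of random sets (-0.16 to 0.01), with 57 higher and 25 lower, 0 called higher and 1 called lower by limma. It was 0.11 in experiment 1 and 0.80 in experiment 2, if the replicate numbers name the experiments. The hypothesis asked for a median under that range, which was not seen. In sid2-2 the median difference from Col-0 at 24 h was 0.38 (random sets -0.08 to 0.03), with 68 higher and 14 lower. Part of the shift in ein2-1 may thus come from the 2 Col-0 arrays shared by both comparisons, which was not tested for this set. A comparison without Col-0 arrays set dde2-2 against ein2-1 at 24 h. Its median difference was -2.41 log2 units (random sets -0.05 to 0.14), with 77 lower and 5 higher in dde2-2. Of these 56 were called lower and 1 higher by limma. This argues against a need for EIN2 as large as that for jasmonate in the set as a whole. Against a smaller need the data argue only if those 2 Col-0 arrays are typical. OSM34, lower in ein2-1 at 24 h, was not selected at 9 h.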
